A study of Rattus norvegicus with 20 samples.

How the data were processed

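RNA from embryonic rat testes was hybridized to Affymetrix rat genome arrays, 20 arrays in 10 groups of 2. The groups were vehicle and vinclozolin at E13, E14 and E16 (12 arrays in utero) and, in culture, DMSO, vinclozolin, ethanol and flutamide (8 arrays). Per the labels, sex was read from a PCR for Sry, and the cultured testes were parted from the mesonephros before RNA was taken.

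The deposited values are signal intensity on a linear scale, made by the authors with the MAS5 algorithm in GCOS and scaled to a common trimmed mean per set of arrays. The versions of MAS5 and GCOS are not given in the sources used here. The trimmed mean (2% of probe sets left out at each end) was checked on the tables and was the same on all arrays of a set, 210.1 in utero, 218.1 in the vinclozolin culture and 107 in the flutamide culture. No further normalization was applied, since the arrays of an experiment shared a scale. Values were taken to log2 after a pseudocount of 16 was added.

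Of 31099 probe sets, 57 control probe sets were left out. A probe set was tested if it reached the 40th percentile of its array on at least 2 arrays, which 22526 did. Gene symbols came from the platform annotation, matched to RefSeq gene names, and locations from the RefSeq genes of the GRCr8 assembly. Of the tested probe sets, 16292 had 1 symbol, 366 several and 5868 none, against 20826, 436 and 9780 of all 31042 without controls. For lists and named genes, the probe set with the highest mean log2 value stood for its gene (11677 genes, of which 3366 had several tested probe sets).

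Probe sets were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group and all 20 arrays in 1 fit, so that the groups shared 1 estimate of the spread (residual degrees of freedom 10, prior degrees of freedom 6.76). Variances were moderated with a trend on mean signal, and p-values, all two-sided, were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The contrasts were vinclozolin minus vehicle at each stage and averaged over the stages, each compound minus its vehicle in culture, the difference of the compounds' effects, and the vehicle testes of E16 minus E13, E14 minus E13 and E16 minus E14. A moderated F test asked whether the effect differed between stages. Intervals are given at a confidence level of 95%.

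Changes in 39 gene lists were tested with camera at a preset correlation of 0.01 between genes, with adjustment over the lists of a comparison, then with an estimated correlation and with fry. Fry tests whether the genes of a list move on balance in 1 direction and does not compare the list with other genes. The lists covered testis and neighbouring cell types, hormone and xenobiotic responses, metabolism, stress, signalling pathways, chromatin and imprinted genes. Genes were named by a rule. In each comparison these were the 10 largest rises and 10 largest falls past the threshold without overlap between the arrays of the groups. Where fewer than 10 passed, they were the 5 of smallest unadjusted p in each direction. Star, Cyp11a1, Cyp17a1, Insl3 and Amh were always named, and list members were taken from the up to 4 of smallest p.

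The alternatives were quantile normalization, pseudocounts of 1 and 64, no filter, a filter at the median, fits with only the arrays of the comparison or of its experiment, the replicate number as a block, no trend, array weights, leaving out each array in turn, the probe set of largest variance per gene, and a rule of unadjusted p under 0.05 with a change of at least 1.5-fold and no overlap between groups. The 2 arrays of a group came out with the same array weight, so that alternative weighted whole groups and not single arrays. When an array was left out, the remaining array of its group was assumed to vary like the other groups. Where the lower group of a named gene lay under the 40th percentile on both arrays, the change was also counted from that percentile. Added after the data were seen were that count, a rescaling of all arrays to 1 trimmed mean, leaving out the E13 arrays numbered 1, and a crossed pairing of the E16 arrays. The mean effect in utero was set against other splits of its 12 arrays within stage, of which 108 exist and 100, the real one included, were used, drawn with seed 1. The fit was tested on simulated data with 200 changed probe sets per comparison, 100 at 2-fold and 100 at 4-fold. The simulated noise was independent and, for each probe set, of the same fitted spread on all arrays. Raw image files and detection calls were not used here.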

Results

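The transcriptome of the embryonic rat testis was measured on 20 oligonucleotide arrays, 2 for each of 10 groups. Testes were collected from Sprague-Dawley embryos on embryonic days 13, 14 and 16 (E13, E14 and E16). The dams had received daily injections of vinclozolin, a fungicide with antiandrogenic metabolites, at 100 mg/kg, or of the vehicle DMSO. The injections ran from E8 to E14, so embryos taken at E13 were collected before their end. In the culture experiments, E13 gonads were kept for 3 days with vinclozolin at 50 µM in DMSO or with flutamide, a pharmaceutical antiandrogen, at 0.5 µM in ethanol. The gonad of the other side of each embryo received the vehicle alone. The labels call the arrays of a group biological replicates but do not say whether they came from separate animals or pools, so the p-values measure the spread between these arrays. With 2 arrays per group, the number of arrays limits the precision, and the median standard error of a difference between groups was 0.24 on the log2 scale.

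The 12 in utero arrays shared a trimmed mean intensity of 210.1, the 4 arrays of the vinclozolin culture 218.1 and the 4 arrays of the flutamide culture 107. Median intensities lay between 40.2 and 71.6. The correlation of log2 values between the arrays of a group, taken across probe sets, ranged from 0.959 to 0.982. The ratio of the 3' to the 5' beta-actin probe sets, a measure of RNA integrity, was 1.73 to 3.47 in utero, 2.67 to 3.90 in the vinclozolin culture and 9.08 to 11.1 in the flutamide culture. Fos, an immediate early transcription factor gene, read 973.9 to 1289.4 on the flutamide culture arrays of both groups. On the other 16 arrays it read 18.3 to 289.2, except 1534.6 on E14 vehicle replicate 1. Fos, Xist and Eif2s3y were singled out after their values were seen.

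Xist, the non-coding RNA that coats an inactive X chromosome (chromosome X, 72540753 to 72558266 in the GRCr8 assembly), was not uniformly low in these male samples. Its probe set of highest mean signal read 758.6 on E13 vehicle replicate 1 and 896 on E13 vinclozolin replicate 1, against 20.4 and 17.9 on the replicates numbered 2. The same arrays numbered 1 had the lower signal of Amh, the Sertoli cell hormone that removes the Müllerian ducts (106 and 372.4, against 1484.7 and 1102.2). At E14, this probe set read 174.9 and 184.4 with vehicle and 32 and 489.9 with vinclozolin. The other Xist probe sets were higher on E14 vehicle replicate 1 than on vehicle replicate 2, at 148.5 and 43.6, 100.1 and 24.3, and 41 and 0.9. With vinclozolin they were higher on replicate 2, as the first probe set was. At E16 it read 2.4 to 16.6, in the vinclozolin culture 5.1 to 5.4 on 3 arrays and 112.8 on vinclozolin replicate 2, and in the flutamide culture 168.2 to 211.9. The Y-linked gene Eif2s3y was present on every array, at 2363.1 to 3495.7 at E13 and E16 and 902.6 to 1248.9 at E14. In culture it read 3115.1 to 3330.2 in the vinclozolin experiment and 668.3 to 764.8 in the flutamide experiment, whose values are on a lower scale.

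**Figure D1:**
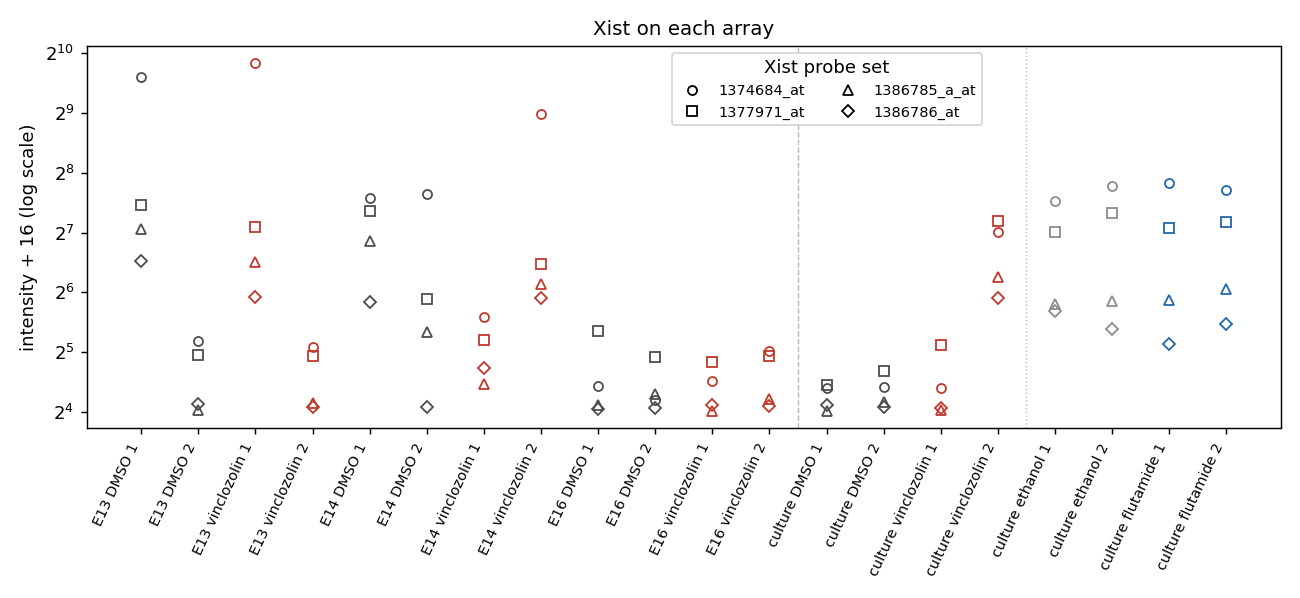
Intensity plus 16 of the 4 Xist probe sets (symbols) on each of the 20 arrays, on a log scale, with vehicle in grey, vinclozolin in red and flutamide in blue. With the probe set drawn as circles, the E13 arrays numbered 1 read 758.6 and 896 and those numbered 2 read 20.4 and 17.9.

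The 3 collection days imply a comparison of vehicle testes over development, and here steroidogenic genes of the fetal Leydig cell, the androgen-producing cell of the testis, were among those that rose the most between E13 and E16. Cyp17a1, the 17-alpha-hydroxylase needed for androgen synthesis (chromosome 1, 255476861 to 255484547), rose by a log2 value of 7.20 (SE 0.39, n = 2 and 2). Cyp11a1, the enzyme that cleaves the cholesterol side chain (chromosome 8, 67318665 to 67330196), rose by 5.71 (SE 0.20) and Hsd3b1, a 3-beta-hydroxysteroid dehydrogenase, by 5.60 (SE 0.35). Insl3, the Leydig cell hormone of testis descent (chromosome 16, 18432668 to 18434539), rose by 5.48 (SE 0.47). Star, which carries cholesterol into the mitochondrion (chromosome 16, 72969824 to 72974447), rose by 2.37 (SE 0.22). Sry, the Y-linked testis-determining gene, fell by 3.14 (SE 0.42). The E13 levels of Cyp17a1, Cyp11a1 and Insl3 and the E16 level of Sry lay under the 40th percentile of their arrays, so the size of these changes depended on the pseudocount. With a pseudocount of 64 the values were 5.79 for Cyp17a1, 4.57 for Cyp11a1, 3.97 for Insl3 and -1.83 for Sry, and counted from that percentile they were 6.39, 5.32, 4.42 and -2.01. The E16 vehicle arrays lay apart for Insl3 (SD 1.36) and Cyp17a1 (SD 0.91). In all, 990 probe sets rose and 935 fell, of 22526 tested.

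Outside steroidogenesis, the largest rises were those of Mgp, the matrix Gla protein (5.81, SE 0.31), Svs5, a seminal vesicle secretory protein (5.43, SE 0.39), the X-linked testis gene Tsx (4.77, SE 0.45), the carboxypeptidase gene Cpa1 (4.70, SE 0.36), the secreted Wnt antagonist Sfrp4 (3.78, SE 0.34) and the globin gene Hba-a3 (3.72, SE 0.69). The largest fall was that of Shisa3, at -3.92 (SE 0.31). Etv2, an ETS factor of endothelial and blood precursors, fell by 2.85 (SE 0.55), the aquaporin gene Aqp3 fell by 2.84 (SE 0.49), the carboxypeptidase gene Cpm by 2.82 (SE 0.23), the lactate transporter gene Slc16a3 by 2.61 (SE 0.27) and Zfp703 by 2.60 (SE 0.30). C1qtnf12 fell by 2.57 (SE 0.31), Cga, the common alpha subunit of the glycoprotein hormones, by 2.56 (SE 0.29) and the homeobox gene Hlx by 2.35 (SE 0.47). The second tested probe set of Cpm stood at -0.12. The lower level of Svs5, Sfrp4, Etv2, Cpm and Cga also lay under the 40th percentile, which leaves their size uncertain. Counted from it, they stood at 4.22 for Svs5, 3.39 for Sfrp4, -1.45 for Etv2, -2.62 for Cpm and -1.90 for Cga. Adjusted p-values of these genes ran from 3.12e-11 for Cyp11a1 to 0.00483 for Hlx. For Amh the difference was 2.38 (SE 0.79, adjusted p = 0.074), with the E13 vehicle arrays far apart.

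Gene lists fixed before the data were examined followed the same division. Of the 17 measured genes of the Leydig cell and steroidogenesis list, 12 rose and 1 fell, the median was 2.33 and camera's adjusted p was 2.28e-13 (adjusted p = 0.00111 with an estimated correlation). Fdx1, the ferredoxin that feeds electrons to Cyp11a1, rose by 2.48 (SE 0.16). Adjusted over the list alone, 12 rose and 2 fell. Of 9 peritubular and smooth muscle genes, 6 rose (8 adjusted over the list alone) and the median was 0.95 (adjusted p = 1.11e-07, and adjusted p = 0.0485 with an estimated correlation). Its members Acta2, smooth muscle actin, rose by 2.38 (SE 0.23), Cnn1, calponin, by 1.94 (SE 0.24, from a level under the 40th percentile, and 1.27 with a pseudocount of 64) and Tagln, transgelin, by 2.17 (SE 0.37). These 2 lists are the ones whose call held with an estimated correlation.

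Another 12 lists were called by camera with its preset correlation alone. Of 16 interstitial and stromal genes, 8 rose and 1 fell (median 1.03, adjusted p = 0.204 with an estimated correlation), among them the proteoglycan genes Ogn (3.23, SE 0.36) and Dcn (3.60, SE 0.41), the Wnt ligand gene Wnt5a (2.09, SE 0.25) and the receptor gene Pdgfra (1.10, SE 0.14). Of 46 extracellular matrix genes, 10 rose and 3 fell (median 0.34, adjusted p = 0.469 with an estimated correlation), and the collagen cross-linking enzyme gene Lox rose by 3.30 (SE 0.28) and the collagen VI genes Col6a1 and Col6a3 by 2.42 (SE 0.20) and 3.05 (SE 0.34). Of 88 respiratory chain genes, 24 rose and 0 fell (median 0.34, adjusted p = 0.444 with an estimated correlation). The respiratory chain members that rose most were Cox7b2 (2.71, SE 0.28, from a level under the 40th percentile, and 1.84 with a pseudocount of 64) and Cox6b2 (1.45, SE 0.23), testis isoforms of cytochrome oxidase subunits. Of 22 hypoxia and glycolysis genes, 8 fell and 2 rose (median -0.51, adjusted p = 0.202 with an estimated correlation). The glycolytic genes Aldoa and Ldha fell by 0.87 (SE 0.14) and 0.82 (SE 0.14), and the angiogenic factor gene Vegfa fell by 1.10 (SE 0.19). Of 20 gonad transcription factor genes, 5 fell and 0 rose (median -0.72, adjusted p = 0.122 with an estimated correlation), among them Nr0b1 (-1.82, SE 0.22) and Wt1 (-0.76, SE 0.14).

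The remaining called lists held few members that passed. They were erythroid genes (6 of 15 rose, median 0.84, adjusted p = 0.578 with an estimated correlation, with the membrane protein gene Epb42 at 2.55, SE 0.43, from a level under the 40th percentile, and at 1.41 with a pseudocount of 64), macrophage genes (4 of 18 rose and 1 fell, median 0.54, adjusted p = 0.444) and cholesterol synthesis genes (3 of 20 rose, median 0.23, adjusted p = 0.516). On the falling side were mesonephros and tubule genes (1 of 18 fell, median -0.65, adjusted p = 0.444), neural genes (2 of 11 fell, median -0.62, adjusted p = 0.0996) and DNA methylation and chromatin enzymes (3 of 29 fell, median -0.34, adjusted p = 0.202), each adjusted p here being that with an estimated correlation. The ribosomal protein list was called at a median of 0.29 (adjusted p = 0.542 with an estimated correlation) although 1 of its 47 genes rose, Rpl39l1 (2.45, SE 0.44), and under quantile normalization its median was 0.03. Adjusted over the list alone, 10 interstitial genes rose and 1 fell, 16 matrix genes rose and 6 fell, 32 respiratory chain genes rose, 14 glycolysis genes fell and 3 rose, and 12 gonad transcription factor genes fell and 1 rose. In the same order for the smaller lists, 6 erythroid, 4 macrophage and 5 cholesterol genes rose, 1 macrophage, 1 mesonephros, 3 neural and 5 chromatin genes fell, and 1 ribosomal gene rose.

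The other 25 lists were not called by camera. Fry, which does not compare a list with other genes, called 15 lists, among them 5 of these 25, the ovary-type supporting cell, sex-chromosome and androgen-responsive lists (each at an adjusted p of 0.0319), the CAR and PXR targets (0.00113) and the IGF and FGF growth factors (0.0477). The Sertoli cell list had a median of 0.09 (5 of 21 rose, 3 fell), germ cells 0.33 (3 of 14 rose), endothelial cells 0.20, adrenal genes -0.18, ovary-type supporting cells -0.21 and the sex-chromosome list -1.55 over 4 genes, with Sry its member that fell. Among hormone and xenobiotic lists, androgen-responsive genes had a median of 0.37, AhR targets -0.30, CAR and PXR targets 0.31 and NRF2 targets 0.09. Fatty acid synthesis stood at -0.02, beta oxidation at 0.21, retinoic acid at -0.13, cell cycle at -0.15, p53 at -0.14, the unfolded protein response at -0.04, heat shock proteins at 0.05, immediate early genes at 0.11 and interferon genes at 0.20. Of the signalling lists, hedgehog stood at 0.29, Notch at -0.10, Wnt at 0.01, TGF-beta at -0.20, the IGF and FGF growth factors at -0.29 and imprinted genes at -0.11.

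In leave-one-out fits the count of changed probe sets was 848 without E13 vehicle replicate 1 and 1099 without E16 vehicle replicate 2. Without these same arrays the adjusted p of Hlx was 0.0621 and 0.0525, and without E13 vehicle replicate 2 the value of Amh was 4.19 with an adjusted p of 0.000416. The erythroid and cholesterol calls ended without E13 vehicle replicate 1 (adjusted p 0.0932 and 0.267), the erythroid and mesonephros calls without E16 vehicle replicate 1 (0.503 and 0.0639), the macrophage call without E13 vehicle replicate 2 (0.0744), and the neural and matrix calls without E16 vehicle replicate 2 (0.0698 and 0.106). With the 4 arrays of the comparison alone, 268 probe sets passed, and Hba-a3, Etv2 and Aqp3 were not among them (adjusted p 0.0859, 0.0748 and 0.107).

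**Figure D2:**
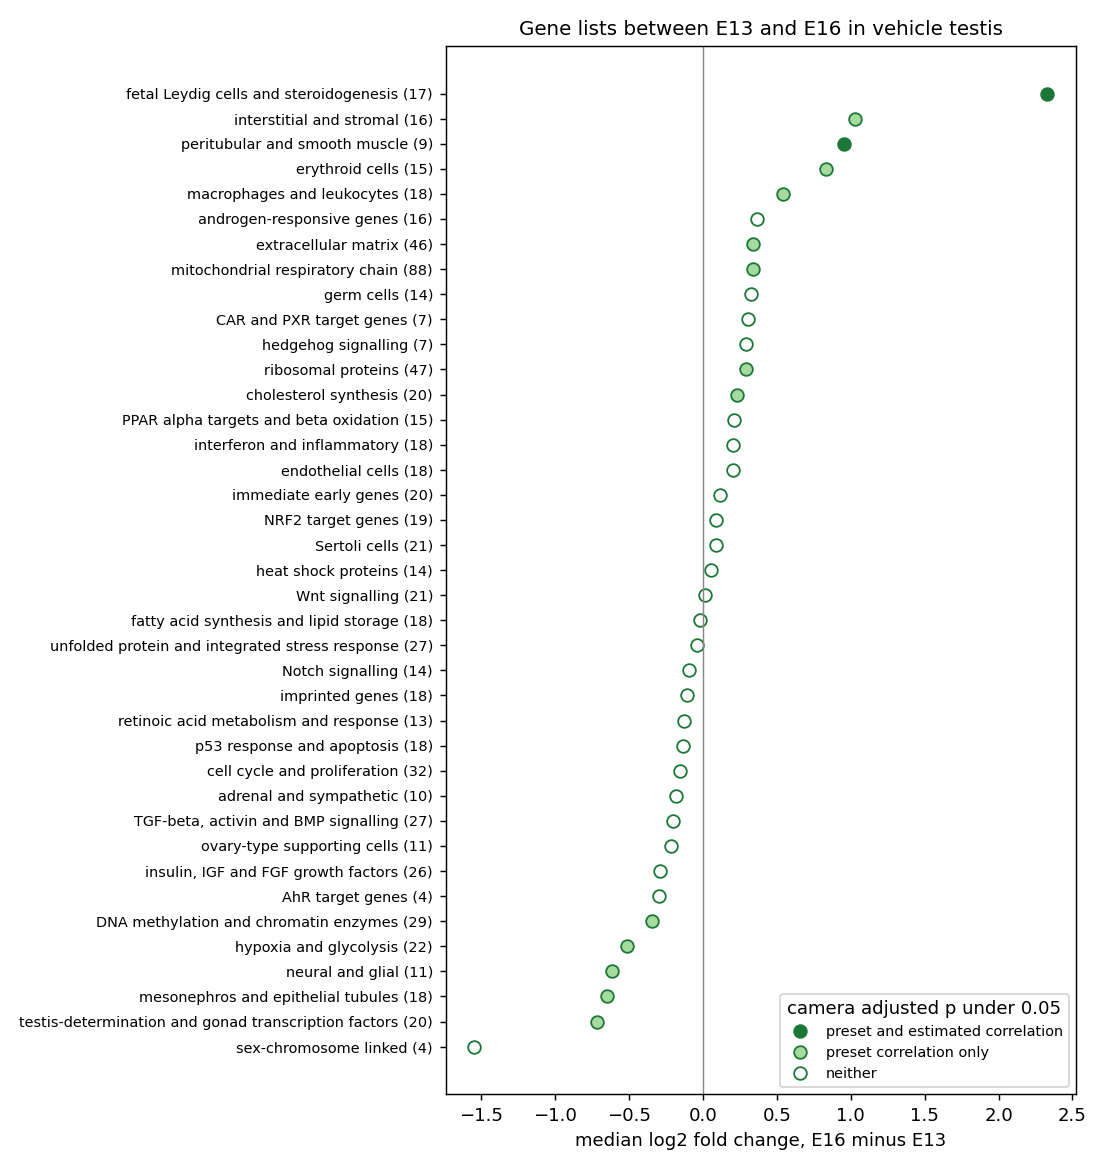
Median log2 fold change of each gene list, E16 minus E13 vehicle testis, with the number of measured genes in brackets. Filled dark points had a camera adjusted p under 0.05 with both a preset and an estimated correlation, as the Leydig cell (2.33) and peritubular (0.95) lists did, pale points with the preset one alone and open points with neither, and under quantile normalization the ribosomal list moved from 0.29 to 0.03.

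Between E13 and E14, structural genes of the extracellular matrix led the rises. The collagen VI genes Col6a3, Col6a2 and Col6a1 rose by 2.85 (SE 0.34), 2.21 (SE 0.29) and 1.97 (SE 0.20), the collagen gene Col8a2 by 2.14 (SE 0.22) and Mgp by 2.14 (SE 0.31). Hsd17b3, the enzyme that makes testosterone from androstenedione, rose by 1.94 (SE 0.45), the kidney cadherin gene Cdh16 by 2.08 (SE 0.52), the aminopeptidase gene Enpep by 2.08 (SE 0.40), the cyclin gene Ccnd2 by 2.02 (SE 0.51) and Tent5c by 1.93 (SE 0.44). The largest falls were those of Pkhd1l1 (-2.10, SE 0.27), Cga (-1.996, SE 0.29), Nup62cl (-1.91, SE 0.42), Sry (-1.76, SE 0.42) and the melanin enzyme gene Dct (-1.73, SE 0.25). Shisa3 (-1.62, SE 0.31), LOC102556108 (-1.56, SE 0.28), Ano5 (-1.54, SE 0.31), Cpm (-1.50, SE 0.23) and the prohormone convertase gene Pcsk2 (-1.47, SE 0.35) completed the falls. In all, 283 probe sets rose and 376 fell; the rises made up 42.9% of the changed probe sets as deposited and 33.1% after quantile normalization, with a median of all probe sets of 0.07 and -0.0029. The lower level of Cdh16, Cga, Ano5 and Pcsk2 lay under the 40th percentile. Counted from it, Cdh16 stood at 1.32, Cga at -1.78, Ano5 at -0.46 and Pcsk2 at -0.61. Of the 5 genes named in every comparison none passed. Cyp11a1 stood at 0.76 (SE 0.20, adjusted p = 0.0508), Insl3 at 0.72 (0.406), Cyp17a1 at -0.02 (0.979), Star at -0.42 (0.277) and Amh at 2.81 (SE 0.79, adjusted p = 0.0657).

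Of 39 lists, camera called 19 between E13 and E14, and 0 with an estimated correlation, where the smallest adjusted p was 0.194, while fry called 12 (smallest adjusted p 0.00797). In the matrix list 7 of 46 genes rose (18 rose and 1 fell adjusted over the list alone, median 0.47, adjusted p = 0.194 with an estimated correlation). In the endothelial list 6 of 18 rose (9 adjusted over the list alone, median 0.45, adjusted p = 0.194 with an estimated correlation), and in the interstitial list 6 of 16 (7 adjusted over the list alone, median 0.29, adjusted p = 0.23 with an estimated correlation), with Pdgfra at 1.11 (SE 0.14) and Wnt5a at 1.78 (SE 0.25). These calls, apart from the interstitial one (0.15 without E14 vehicle replicate 1), held without each array in turn. Camera also called the sex-chromosome list, in which 2 of 4 genes fell (median -0.68, adjusted p = 0.194 with an estimated correlation). The Y-linked Eif2s3y read 1237.5 and 1248.9 on the E14 vehicle arrays, against 2363.1 and 2594.5 at E13 and 2364.2 and 3495.7 at E16. Uty, also Y-linked, read 443.3 and 447.1 at E14, against 650.3 and 526.4 at E13 and 514.8 and 645.7 at E16. The fall of Sry thus went with lower values of both. The Leydig list was called too, with 2 of 17 genes risen (3 adjusted over the list alone) and a median of 0.41. Its adjusted p was 0.0249 with camera, 0.194 with an estimated correlation and 0.00958 with fry. The largest median among the called lists was 0.80, of immediate early genes (1 of 20 rose, adjusted p = 0.305 with an estimated correlation). E14 vehicle replicate 1 held the highest E14 value for 16 of these 20. The Sertoli list was called at a median of 0.52 with 1 of 21 genes past the threshold, Nr0b1, which fell by 1.36 (SE 0.22); its adjusted p was 0.65 with an estimated correlation and 0.528 without E13 vehicle replicate 1.

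The count of 659 was 71 without E14 vehicle replicate 1, 197 without E13 vehicle replicate 2, and 0 with the 4 arrays of the comparison alone. Of the named genes, Col6a3, Col6a2, Col6a1, Col8a2, Mgp, Pkhd1l1, Cga, Cpm, Pdgfra and Wnt5a kept their call without each array in turn, Dct and LOC102556108 and Nr0b1 lost it only without E14 vehicle replicate 1 (adjusted p 0.0503, 0.098 and 0.0713), and the other named genes lost it in at least 1 such fit. Without E13 vehicle replicate 1 these were Enpep (0.0599), Hsd17b3 (0.14), Tent5c (0.116), Nup62cl (0.117), Sry (0.137), Shisa3 (0.0618), Ano5 (0.0545) and Pcsk2 (0.127); without E13 vehicle replicate 2 they were Cdh16 (0.229), Ccnd2 (0.335), Ano5 (0.0647) and Pcsk2 (0.0655), while Amh passed (4.62, adjusted p = 0.0012). Without E14 vehicle replicate 1 they were Cdh16 (0.31), Enpep (0.057), Ccnd2 (0.23), Tent5c (0.199), Sry (0.195) and Ano5 (0.0677). Without E14 vehicle replicate 2 they were Enpep (0.0641), Ccnd2 (0.0525), Hsd17b3 (0.173), Nup62cl (0.14), Shisa3 (0.0834), Ano5 (0.0662) and Pcsk2 (0.2), while Cyp11a1 passed (1.13, adjusted p = 0.00733).

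Between E14 and E16 the Leydig genes rose steeply. Cyp17a1 rose by 7.22 (SE 0.39), Cyp11a1 by 4.95 (SE 0.20), Insl3 by 4.76 (SE 0.47), Hsd3b1 by 4.09 (SE 0.35) and Star by 2.79 (SE 0.22). Svs5 rose by 5.38 (SE 0.39), Cpa1 by 5.06 (SE 0.36), Sfrp4 by 4.17 (SE 0.34), Mgp by 3.67 (SE 0.31), Sycp3, a component of the meiotic chromosome axis, by 3.23 (SE 0.46) and the carbonic anhydrase gene Car1 by 3.12 (SE 0.46). The tight junction genes Cldn8 and Cldn6 fell by 2.95 (SE 0.59) and 2.89 (SE 0.65), Cdh16 by 2.77 (SE 0.52), the surface glycoprotein gene Thy1 by 3.11 (SE 0.74) and Aqp3 by 2.44 (SE 0.49). Arid3a fell by 2.37 (SE 0.42), Zfp703 by 2.34 (SE 0.30), the actin-bundling gene Fscn1 by 2.31 (SE 0.60), Shisa3 by 2.30 (SE 0.31) and the adrenergic receptor gene Adra2a by 2.23 (SE 0.46). The lower level of Cyp17a1, Insl3, Svs5, Sfrp4, Car1, Thy1, Cldn8, Cldn6, Cdh16 and Arid3a lay under the 40th percentile. Counted from it, Cyp17a1 rose by 6.23, Insl3 by 4.27, Svs5 by 4.06, Sfrp4 by 3.24 and Car1 by 1.79. From the same level Thy1 stood at -2.69, Cldn8 at -1.62, Cldn6 at -1.56, Cdh16 at -1.28 and Arid3a at -1.04. Amh stood at -0.43 (SE 0.79, adjusted p = 0.734), and at 0.50 without E14 vehicle replicate 2. In all, 2112 probe sets rose and 2845 fell; the median of all probe sets was -0.10 as deposited and -0.01 after quantile normalization, and the rises made up 42.6% of the changed probe sets as deposited and 53.1% after it.

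Camera called 13 lists between E14 and E16, 5 higher and 8 lower, and fry 17 (smallest adjusted p 7.08e-08). Of the 13, the Leydig list kept its call with an estimated correlation (11 of 17 rose and 1 fell, also adjusted over the list alone, median 1.81, adjusted p = 0.0132). Mesonephros and tubule genes had a median of -1.07 and 8 of 18 fell (14 fell and 1 rose adjusted over the list alone; adjusted p = 0.0123 without E14 vehicle replicate 1, which held the highest E14 value for 14 of the 18), peritubular genes 1.16 with 7 of 9 rising (7 adjusted over the list alone) and respiratory chain genes 0.41 with 37 of 88 rising (47 adjusted over the list alone). With an estimated correlation their adjusted p was 0.484 for the mesonephros list, 0.213 for the peritubular list and 0.484 for the respiratory chain list. The other rising lists were cholesterol synthesis (0.32) and ribosomal genes (0.31, and 0.09 with an adjusted p of 0.0933 after quantile normalization), and the other falling ones immediate early (-0.69), TGF-beta (-0.54), gonad transcription factor (-0.51), IGF and FGF growth factor (-0.49), endothelial (-0.44), glycolysis (-0.31) and chromatin genes (-0.25), with adjusted p = 0.298 to adjusted p = 0.605 with an estimated correlation. At their largest leave-one-out adjusted p, the cholesterol (0.317), immediate early (0.719), TGF-beta (0.317) and glycolysis (0.0865) calls ended without E14 vehicle replicate 1 and the endothelial (0.0805), gonad transcription factor (0.158) and chromatin (0.124) calls without E14 vehicle replicate 2. Leaving out single arrays moved the count to between 2846 (without E16 vehicle replicate 2) and 2983 (without E14 vehicle replicate 2), with 2925 and 2930 without the replicates numbered 1 of E14 and E16, and ended the calls of Thy1 and Cldn6 without E14 vehicle replicate 1 (adjusted p 0.11 and 0.0836) and of Fscn1 without E14 vehicle replicate 2 and E16 vehicle replicate 1 (0.0785 and 0.104). With the 4 arrays of the comparison alone, 1796 probe sets passed and Thy1, Aqp3 and Adra2a had adjusted p-values of 0.0703, 0.0538 and 0.0547.

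**Figure D3:**
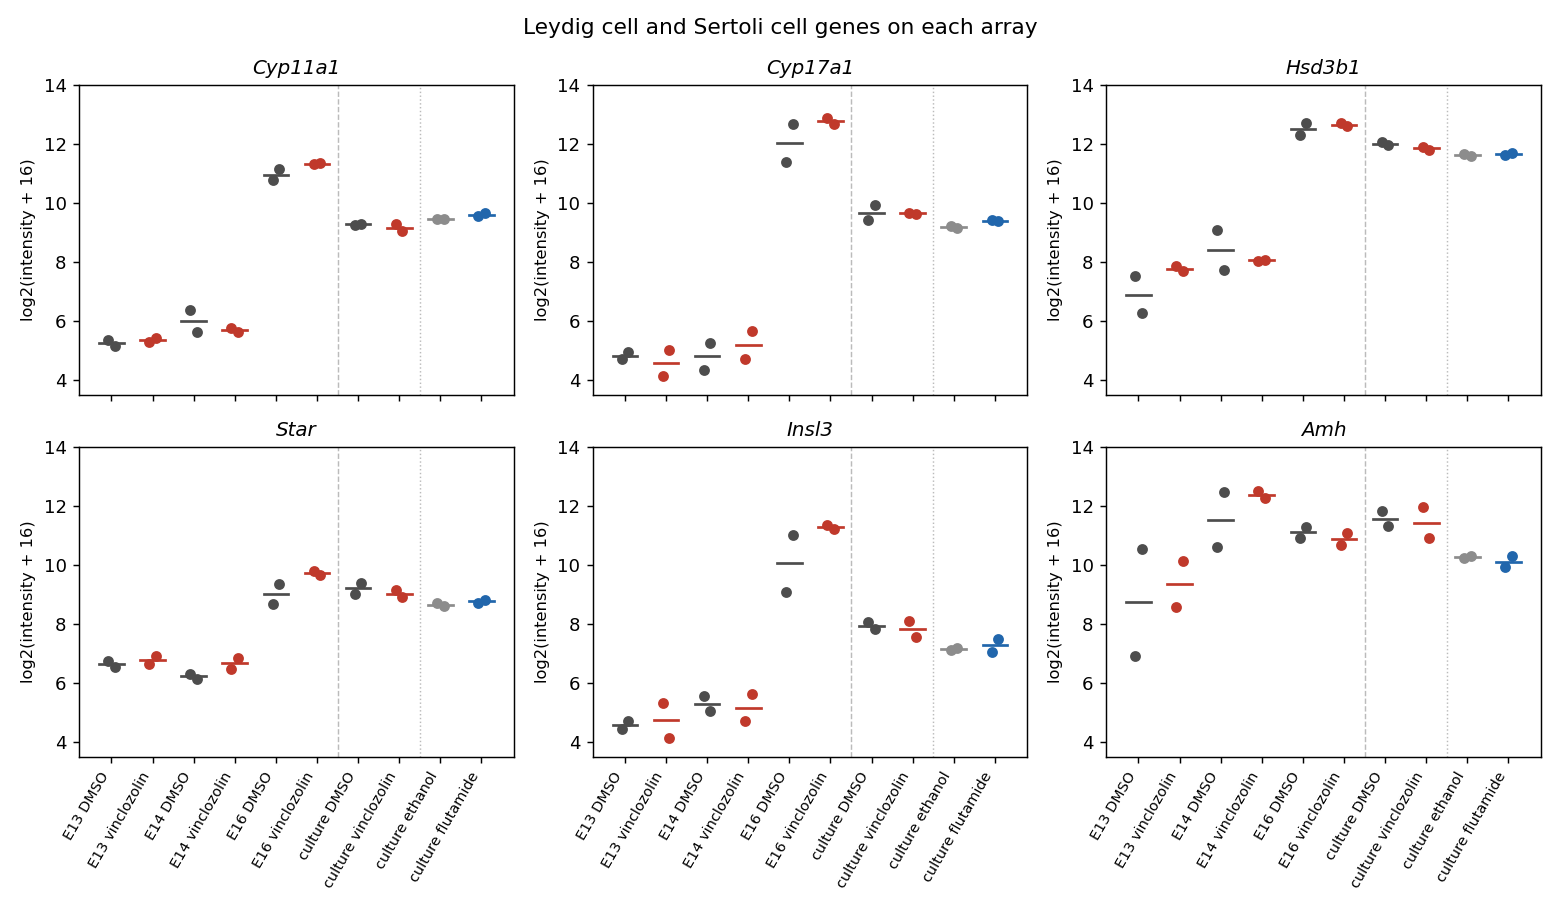
log2(intensity + 16) of 5 Leydig cell genes and of Amh on each array (points; vehicle grey, vinclozolin red, flutamide blue) with the group means (lines), on the deposited scale; the dashed line parts in utero from culture arrays and the dotted line the culture experiments, whose scales differ. Cyp17a1 rose by 7.20 between E13 and E16 with vehicle from a level under the 40th percentile, and at E16 its level with vinclozolin differed from that with vehicle by 0.75 (SE 0.39), which did not pass the test.

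Vinclozolin in utero was compared with vehicle at E13, a day on which the dams were still being treated. No steroidogenic gene passed the test, with Star at 0.13 (SE 0.22), Cyp11a1 at 0.11 (SE 0.20), Cyp17a1 at -0.24 (SE 0.39), Insl3 at 0.17 (SE 0.47) and Hsd3b1, of smallest p in the Leydig list, at 0.87 (SE 0.35, unadjusted p = 0.0234). The 10 genes with the smallest p-values had values of 1.32 for Gda, the guanine deaminase gene (SE 0.35), 1.46 for the histone demethylase gene Kdm4d (SE 0.41), 0.98 for the amino acid transporter gene Slc36a2, 0.64 for Nostrin and 0.56 for Phf14, and of -1.03 for Ankrd16, -1.09 for Mamdc2, -1.08 for Prcd, -0.66 for Rab33a and -0.93 for Pcsk4. None passed, since their adjusted p was 1. For Amh the value was 0.62 (SE 0.79).

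With limma, 0 probe sets rose and 0 fell at E13, and 402 had an unadjusted p under 0.05, against 1126 that chance would give. The deviations of equal numbers correlated at 0.602 at E13 and the fit did not pair the arrays, so its errors there may be too large. Camera called 4 of the 39 lists, and 0 were called with an estimated correlation or by fry. All 9 peritubular and smooth muscle genes were lower with vinclozolin (median -0.31, adjusted p = 0.001, and adjusted p = 0.588 with an estimated correlation), with the actin gene Actg2 at -0.66 (SE 0.27) and Cnn1 at -0.49 (SE 0.24). The adrenal list had a median of 0.40, the endothelial list 0.08 and the ribosomal list 0.05, which became -0.0041 after quantile normalization, and each of the 3 had an adjusted p of 0.984 with an estimated correlation. In the 4 lists 0 members passed over all genes or adjusted over the list alone. The peritubular call ended without E13 vinclozolin replicate 2 (adjusted p 0.0994), the adrenal and endothelial calls without E13 vehicle replicate 2 (0.331 and 0.83) and the ribosomal call without E13 vehicle replicate 1 (0.821). Without E13 vehicle replicate 1, 4 probe sets passed and the Amh value was -1.19. The directions of the small differences also rested on single arrays, since without E13 vinclozolin replicate 1 Cyp17a1 stood at 0.20 and Insl3 at -0.42, and without E13 vinclozolin replicate 2 Star stood at -0.018.

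At E14, the last day of treatment, 1 gene passed the test. RT1-Bb, a beta chain of the MHC class II molecule (1 tested probe set, chromosome 20, 4598475 to 4604118), rose by 3.06 (SE 0.38, adjusted p = 0.00855). Its vehicle level lay under the 40th percentile, and the value was 4.44 with a pseudocount of 1, 1.76 with a pseudocount of 64 and 1.80 counted from that percentile. Next to it were Prss35, a serine protease homologue, at -1.61 (SE 0.26, adjusted p = 0.119) and Ephx2, soluble epoxide hydrolase, at -1.40 (SE 0.24, adjusted p = 0.184). With an adjusted p of 0.888 followed Cenpt (0.81), Gpr137b (0.69), LOC102549521 (1.31), Dlgap4 (0.59), Dhx40 (-0.78), Lrfn5 (-1.34) and Akap12 (-0.89), and the other 3 probe sets of Gpr137b stood at -0.46, 0.38 and 0.25. Star stood at 0.44 (SE 0.22), Cyp11a1 at -0.31 (SE 0.20), Cyp17a1 at 0.38 (SE 0.39), Insl3 at -0.13 (SE 0.47) and Amh at 0.83 (SE 0.79).

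Without E14 vehicle replicate 1 the values of Cyp11a1, Cyp17a1, Insl3 and Amh had the opposite direction, at 0.06, -0.08, 0.12 and -0.10. The call of RT1-Bb ended without E14 vehicle replicate 1 (3.15, adjusted p = 0.137) and without E14 vinclozolin replicate 1 (2.81, adjusted p = 0.118), with a pseudocount of 1 (adjusted p = 0.301), with array weights (0.388) and with the 4 arrays of the comparison alone (0.0639). Over the 22526 probe sets, 1239 had an unadjusted p under 0.05, against 1126 that chance would give. The count of calls was 0 without E14 vehicle replicate 1, 272 without E14 vehicle replicate 2 (100 higher, 172 lower), 2 without E14 vinclozolin replicate 1 and 3 without E14 vinclozolin replicate 2. In the fit without E14 vehicle replicate 2, the genes Dlgap4 (adjusted p 0.0393), Prss35 (0.0452), Ephx2 (0.0486), Dhx40 (0.0485), Lrfn5 (0.035) and Akap12 (0.0315) passed, and Prss35 also passed without E14 vinclozolin replicate 1 (0.0359).

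Camera called 14 of the 39 gene lists at E14, against 4 at E13 and 4 at E16, and 0 of the 14 with an estimated correlation (adjusted p = 0.461 to adjusted p = 0.807). Sertoli cell genes (19 of 21 higher, median 0.54) and germ cell genes (12 of 14 higher, median 0.46) sat higher with vinclozolin, as Gata4 (0.85, SE 0.33) and Sall4 (1.23, SE 0.58) did. Interstitial genes had a median of -0.33, macrophage genes -0.51, erythroid genes -0.38, mesonephros genes -0.31, adrenal genes -0.55, neural genes -0.37, retinoic acid genes -0.49 and immediate early genes -0.31. Members with the smallest p were Ogn (-1.15, SE 0.36) among interstitial genes, Cd53 (-0.92, SE 0.30) among macrophage genes, the tight junction gene Cldn3 (-1.44, SE 0.41) among mesonephros genes, and Chgb, chromogranin B (-1.58, SE 0.45), and Cyp11b1, the adrenal 11-beta-hydroxylase (-1.21, SE 0.40), among adrenal genes. In the neural list Stmn2 stood at -0.94 (SE 0.28) and the nerve growth factor receptor gene Ngfr at 1.27 (SE 0.44). Respiratory chain genes had a median of -0.07, Wnt genes -0.21, TGF-beta genes -0.23 and ribosomal genes -0.17, which became 0.03 after quantile normalization. Fry called 0 lists. Over all genes 0 members passed; adjusted over the list alone, 1 mesonephros, 2 adrenal and 1 neural gene fell and 0 members of the other 11 lists passed.

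Many of these E14 shifts went with 1 vehicle array, replicate 1. It held the highest of the 4 E14 values for 15 of 15 erythroid, 15 of 18 macrophage, 14 of 16 interstitial, 14 of 18 mesonephros, 8 of 10 adrenal, 39 of 47 ribosomal and 16 of 20 immediate early genes, and its Fos intensity was 1534.6, against 39.8 on vehicle replicate 2. These lists were called as lower with vinclozolin, which by itself favours a vehicle array. Vehicle replicate 2, however, held the highest value for 0 erythroid, 0 macrophage, 0 interstitial, 2 mesonephros, 1 adrenal, 1 ribosomal and 0 immediate early genes. Vinclozolin replicate 1 stood apart as well, at -42.2 on the second principal component of the in utero arrays against -18.8 to -8.94 on the other E14 arrays, and held the highest E14 value for 14 of 21 Sertoli, 12 of 18 endothelial and 46 of 88 respiratory chain genes. On the third component it stood at -22.25. Vehicle replicate 1 did not stand apart on these components, at -8.94 and 14.31, against -18.82 and 7.03 for vehicle replicate 2 and -14.18 and 8.16 for vinclozolin replicate 2. Without vehicle replicate 1, 4 of the 14 lists were still called in the same direction, against 12 without vehicle replicate 2 and 7 without either vinclozolin array, and the largest leave-one-out adjusted p, reached without this array, was 0.994 for the Sertoli, 0.953 for the germ cell, 0.314 for the interstitial, 0.544 for the erythroid, 0.816 for the mesonephros, 0.813 for the adrenal and the retinoic acid, 0.975 for the Wnt and 0.994 for the TGF-beta list. The neural and respiratory chain calls ended without E14 vehicle replicate 2 (adjusted p 0.292 and 0.244), the immediate early call without E14 vinclozolin replicate 2 (0.105) and the ribosomal call without E14 vinclozolin replicate 1 (0.0849). Of the members named for these lists, Gata4 (adjusted p 0.0133), Sall4 (0.0232), Ogn (0.00248), Cd53 (0.0239), Cldn3 (0.00656), Chgb (0.00721), Cyp11b1 (0.04) and Ngfr (0.00124) passed without E14 vehicle replicate 2, and Sall4 stood at -0.0094 without E14 vehicle replicate 1.

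**Figure D4:**
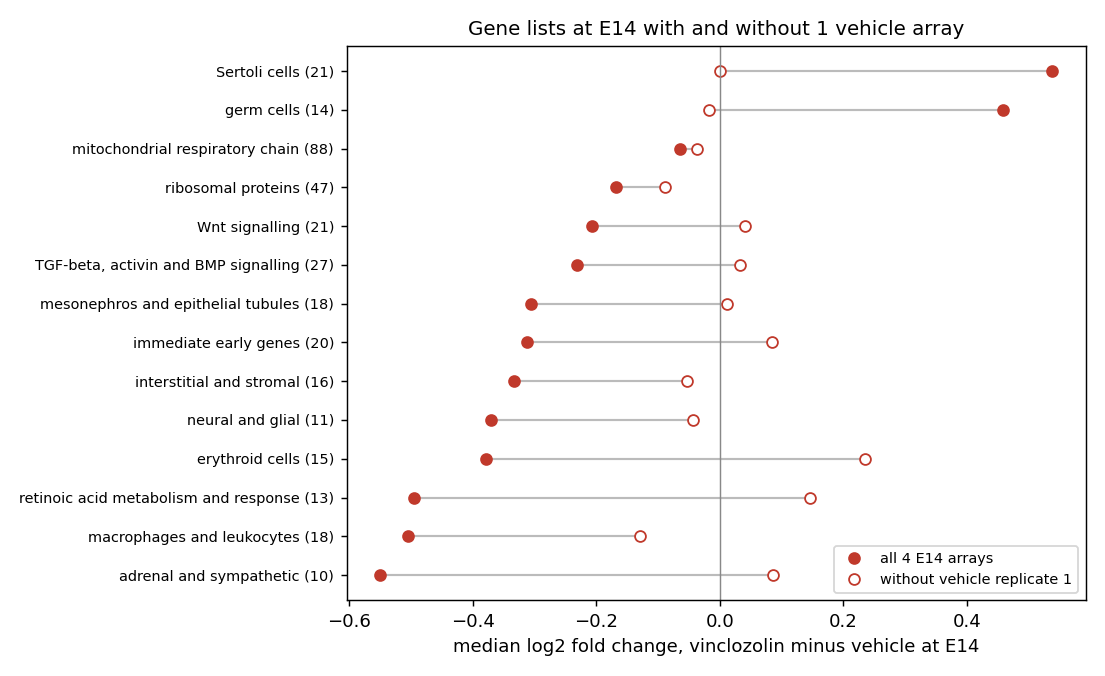
Median log2 fold change at E14, vinclozolin minus vehicle, of the 14 lists called by camera, with all 4 arrays (filled) and without vehicle replicate 1 (open). The adrenal list moved from -0.55 to 0.09 and the Sertoli list from 0.54 to -0.00060; the ribosomal list stood at -0.17 as deposited and at 0.03 after quantile normalization.

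At E16, after the end of treatment, the Leydig genes had higher values with vinclozolin that did not pass the test. Insl3 stood at 1.23 (SE 0.47, adjusted p = 0.634) and Cyp17a1 at 0.75 (SE 0.39, adjusted p = 0.773). Star stood at 0.71 (SE 0.22, adjusted p = 0.579) and Cyp11a1 at 0.37 (SE 0.20, adjusted p = 0.781), while Amh stood at -0.24 (SE 0.79). The E16 vehicle arrays lay far apart for Insl3 (SD 1.36) and Cyp17a1 (SD 0.91), while these SE came from a spread shared by all groups. The smallest adjusted p was 0.47, for Cdh1, the epithelial cadherin gene, at 1.24 (SE 0.27). With an adjusted p of 0.508 followed the host gene of small nucleolar RNAs Snhg11 (1.55, with its other 3 probe sets at 1.13 to 1.17), Nedd1 (0.94), Prcd (1.19), the laminin gene Lama1 (0.73), Pir (-0.58), Apba3 (-0.90), Mocs2 (-0.87), Zfp263 (-1.42) and the MHC class I gene RT1-N2 (-1.32).

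With limma, 0 probe sets rose and 0 fell at E16, and 1506 had an unadjusted p under 0.05, of which 1183 were higher and 323 lower with vinclozolin. After quantile normalization 896 were higher and 603 lower, and the median of all probe sets was 0.04 as deposited and -0.01 after it. Without E16 vehicle replicate 2, 24 rose and 4 fell, Cdh1 among those that rose (1.66, adjusted p = 0.0441). Camera called 4 lists. Of the 17 Leydig genes 12 were higher (median 0.15, adjusted p = 0.0309, and adjusted p = 0.559 with an estimated correlation), with the lipoprotein receptor gene Scarb1 at 0.64 (SE 0.25), and all 9 peritubular genes were lower (median -0.22, adjusted p = 0.788 with an estimated correlation), with Cnn1 at -0.48 (SE 0.24). Hypoxia and glycolysis genes had a median of 0.11 and respiratory chain genes -0.11, both with an adjusted p of 0.83 with an estimated correlation, and fry called 0 lists. In these lists 0 members passed over all genes or adjusted over the list alone. The Leydig call ended without E16 vehicle replicate 1 (adjusted p 0.253) and vinclozolin replicate 1 (0.0834), the peritubular call without vehicle replicate 2 (0.297) and vinclozolin replicate 1 (0.296), the glycolysis call without vinclozolin replicate 1 (0.407) and the respiratory chain call without vinclozolin replicate 2 (0.657).

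Averaged over E13, E14 and E16, with 6 treated and 6 vehicle arrays, the steroidogenic gene Star stood at 0.43 (SE 0.13), Cyp17a1 at 0.30 (SE 0.23), Insl3 at 0.42 (SE 0.27), Cyp11a1 at 0.06 (SE 0.12) and Amh at 0.41 (SE 0.46), each with an adjusted p of 0.998. Ephx2 stood at -0.82 (SE 0.14, adjusted p = 0.274) and RT1-Bb at 1.27 (SE 0.22, adjusted p = 0.274). The remaining genes of smallest p, at an adjusted p of 0.998, were Rnf213 (0.81), Cmip (0.57), Noxo1 (0.82) and LOC102549521 (0.77) on the higher side and Prss35 (-0.68), Mfsd10 (-0.99), Stmn2 (-0.60) and Sulf2 (-0.38) on the lower side. With limma 0 probe sets passed, and 923 had an unadjusted p under 0.05, against 1126 that chance would give. Here too the E13 arrays were not paired by number. Without E14 vehicle replicate 2, 9 passed, and without E13 vinclozolin replicate 1, 2 passed, Ephx2 (-0.96) and Mfsd10 (-1.30), both at an adjusted p of 0.016. With a pseudocount of 64, RT1-Bb passed (0.71, adjusted p = 0.0282).

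Camera called 11 lists for the mean effect and 0 with an estimated correlation, and fry called 0. Higher were the Sertoli (median 0.22, 18 of 21 genes), germ cell (0.29, 12 of 14) and Leydig (0.15, 13 of 17) lists, with the claudin gene Cldn11 at 0.32 (SE 0.10) among Sertoli genes. Lower were the erythroid (-0.35, 15 of 15), macrophage (-0.14), interstitial (-0.13), peritubular (-0.09), heat shock (-0.09), Wnt (-0.10), respiratory chain (-0.06) and ribosomal (-0.06) lists. With an estimated correlation the adjusted p was 0.619 for the Sertoli, germ cell, Leydig, macrophage, interstitial, peritubular and heat shock lists, and adjusted p = 0.716 for the erythroid and respiratory chain, 0.714 for the Wnt and 0.886 for the ribosomal list. In these lists 0 members passed over all genes or adjusted over the list alone. The Sertoli and germ cell calls ended without 1 of 12 arrays, E14 vehicle replicate 1 (adjusted p 0.31 and 0.0779), as did, at their largest adjusted p, the interstitial (0.512), macrophage and Wnt calls (both 0.476). The others were largest without E14 vehicle replicate 2 for the Leydig list (0.285), E14 vinclozolin replicate 2 for the peritubular (0.319), heat shock (0.189) and respiratory chain (0.59) lists, E14 vinclozolin replicate 1 for the ribosomal (0.481) and E16 vehicle replicate 1 for the erythroid list (0.62).

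Whether the vinclozolin effect differed between the 3 stages was tested with limma's moderated F test. The stages also differed in the length of exposure or the time since its end, so stage and exposure cannot be told apart. RT1-Bb had the smallest p, with values of 0.50 at E13, 3.06 at E14 and 0.24 at E16 and an adjusted p of 0.904, so its difference between stages did not pass. Phf14 (0.56, -0.64 and -0.40), Prcd (-1.08, -0.10 and 1.19), Prss35 (0.21, -1.61 and -0.63) and Msmp (0.98, 0.32 and -1.06) followed at 0.983 for the same stages. In total 0 probe sets passed, and 1004 had an unadjusted p under 0.05. Leaving out E13 vehicle replicate 1, E14 vehicle replicate 2 or either E14 vinclozolin array gave 1.

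In culture, E13 testes exposed to vinclozolin for 3 days showed no steroidogenic gene past the threshold. Star stood at -0.19 (SE 0.22), Cyp11a1 at -0.11 (SE 0.20), Cyp17a1 at -0.02 (SE 0.39), Insl3 at -0.11 (SE 0.47) and Amh at -0.14 (SE 0.79). The genes of smallest p were Ncf4, a subunit of the phagocyte oxidase (1.34, SE 0.34), Cnksr3 (0.87), Aldh16a1 (0.71), Pou2f2 (1.16, with another probe set at -0.35), Phf7 (0.97), Retreg3 (-1.18, SE 0.28), the endoplasmic reticulum protein disulfide isomerase gene Pdia3 (-0.80), Aph1a, a subunit of gamma-secretase (-1.12), Arrdc4 (-0.82) and the spliceosome gene Snrpd3 (-0.70). Their adjusted p was 1, so none passed. Limma called 0 probe sets, 610 had an unadjusted p under 0.05, and all leave-one-out counts were 0. Without vinclozolin replicate 2 Insl3 stood at 0.17 and Amh at 0.39, and without vehicle replicate 2 Cyp17a1 stood at 0.23.

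Of the 39 lists camera called 2 in this culture and fry 0. Of 14 germ cell genes 13 were higher (median 0.48, adjusted p = 0.00769, and adjusted p = 0.966 with an estimated correlation), with Piwil2, a piRNA-binding protein gene, at 0.66 (SE 0.27) and the homeobox gene Rhox9 at 0.69 (SE 0.33). The germ cell call ended without vehicle replicate 1 (adjusted p 0.807) and vinclozolin replicate 2 (0.451). The ribosomal list had a median of 0.15 (adjusted p = 0.966 with an estimated correlation), and of -0.03 without vinclozolin replicate 2 (adjusted p 0.218). In both lists 0 members passed over all genes or adjusted over the list alone. Vinclozolin replicate 2 was the array of this culture with the higher Xist signal and with the highest 3' to 5' ratios, 3.90 for beta-actin (2.67 to 3.12 on the other 3) and 1.53 for Gapdh (1.22 to 1.39).

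Flutamide in culture likewise took no steroidogenic gene past the threshold. Star stood at 0.11 (SE 0.22), Cyp11a1 at 0.14 (SE 0.20), Cyp17a1 at 0.23 (SE 0.39), Insl3 at 0.10 (SE 0.47) and Amh at -0.16 (SE 0.79). Zfp523 stood at 1.65 (SE 0.32, adjusted p = 0.961, with another probe set at 0.09) and Tcea2, an elongation factor gene, at -1.26 (SE 0.25, adjusted p = 0.961). At an adjusted p of 1 followed Tepsin (0.63), Dnaaf8 (1.01), the coactivator gene Ncoa3 (1.08), Rusc2 (0.79), Palmd (-1.25, with other probe sets at 0.37 and 0.42), Phldb3 (-0.997), the purinergic receptor gene P2ry6 (-0.89) and Tradd, an adaptor of the TNF receptor (-0.85). Limma called 0 probe sets, in the leave-one-out fits too, and 494 had an unadjusted p under 0.05. With array weights 3 passed, Zfp523 and Tcea2 among them (both at an adjusted p of 0.0302), and with a pseudocount of 1, 4 passed, Tcea2 among them (0.025). Camera called 1 list, the respiratory chain (median -0.08, 68 of 88 lower, adjusted p = 0.0129, and adjusted p = 0.975 with an estimated correlation), with Ndufb9 at -0.37 (SE 0.16) and 0 members past the threshold over all genes or adjusted over the list alone. That median was 0.02 without flutamide replicate 1 (adjusted p 0.841), and fry called 0 lists.

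Vinclozolin and flutamide, both nonsteroidal antiandrogens, were set side by side as the difference of their effects in culture. They were given at 50 µM in DMSO and 0.5 µM in ethanol, so dose and vehicle differed as well as the compound. RNA integrity and scale differed too. The beta-actin ratio was 9.08 to 11.1 in the flutamide culture and 2.67 to 3.90 in the vinclozolin culture. The pseudocount was 14.9% and 7.3% of their trimmed means, which damps log2 changes more in the flutamide culture. The difference therefore does not isolate the compound. The fit did not pair the 2 gonads of an embryo, since the labels do not say which arrays share embryos. For Star the difference was -0.29, with a 95% interval of -0.94 to 0.35, for Cyp11a1 -0.25 (-0.86 to 0.35), for Cyp17a1 -0.25 (-1.42 to 0.93), for Insl3 -0.21 (-1.63 to 1.21) and for Amh 0.02 (-2.35 to 2.39), a value that was -0.015 after quantile normalization. The intervals of the genes of smallest p were wide, such as 0.70 to 2.10 around 1.40 for P2ry6 and -2.73 to -0.82 around -1.77 for Zfp523. The others were Angptl4, an inhibitor of lipoprotein lipase (1.00), Tomm40l (1.28), Lrch4 (1.34), Phf7 (1.44), the condensin gene Smc4 (-1.49, with another probe set at 0.25), Dip2c (-1.76), Retreg3 (-1.32) and Arhgdig (-1.79), all at an adjusted p of 1. Limma called 0 probe sets, 563 had an unadjusted p under 0.05, and 0 lists were called by camera, with an estimated correlation or by fry. In simulated data of this design, with folds set after the pseudocount was added, 10% of 2-fold and 76% of 4-fold differences between the effects were found. Smaller differences between the compounds were thus mostly not detectable.

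The list of androgen-responsive genes, 16 measured, was not called by camera or fry in any treatment comparison, and 0 members passed. Their median was 0.01 at E13, 0.06 at E14, -0.05 at E16, 0.04 for the mean in utero, 0.08 with vinclozolin in culture and 0.03 with flutamide in culture. The marker genes Sox9, Ddx4 and Pou5f1 were not analysed here. Across probe sets, which are not independent replicates, the correlation of effects between the 5 treatment comparisons, 10 pairs in all, lay between -0.27 (E13 with E14) and 0.22 (E13 with E16), and was -0.08 between vinclozolin and flutamide in culture. No probe set was called in 2 comparisons, as E14 alone had a call. Simulated 4-fold changes were found in 93% or more of cases in each of the 5 treatment comparisons and 2-fold changes in 38% to 55%. The folds were set after the pseudocount was added. A low signal moves by less than its fold of intensity there, so the shares are too high for genes of low signal. The simulated noise was independent and of equal spread on all arrays. The real data held arrays that stood apart and, at E13, a difference shared by number, so these shares need not hold there.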

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

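The tests of the Xist probe sets and of dilution at E13, the correlation without E14 vehicle replicate 1, all tests of the E14 lists, the splits that did not part the E13 arrays by number, and at E16 the test with quantile normalization and the interval criterion for single arrays were chosen after the result was seen.

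Differences between groups in the effect of vinclozolin were picked out where camera called a list for the difference itself, at an adjusted p under 0.05 with the preset correlation. None of the 16 was called with an estimated correlation, where the adjusted p ran from 0.395 to 0.905. The effect at E14 minus that at E13 had a median of -1.01 for adrenal, -0.54 for macrophage, -0.37 for interstitial, -0.23 for immediate early, -0.22 for ribosomal and -0.18 for imprinted genes, and of 0.40 for Sertoli and 0.48 for peritubular genes. These rest in part on E14 vehicle replicate 1, without which the E14 median moved from -0.55 to 0.09 for adrenal, from -0.51 to -0.13 for macrophage, from -0.33 to -0.05 for interstitial and from 0.54 to -0.00060 for Sertoli genes. The ribosomal medians at E13 and at E14 changed sign after quantile normalization, as given above. The effect at E16 minus that at E13 had a median of -0.26 for macrophage, -0.20 for endothelial and -0.12 for ribosomal genes. The effect in culture minus the mean effect in utero had a median of -0.25 for Leydig, -0.15 for Sertoli, 0.24 for neural, 0.21 for ribosomal and 0.22 for Wnt genes. In culture the ribosomal median changed sign without vinclozolin replicate 2.

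At E13 the arrays numbered 1 of both groups carried a high Xist and a low Amh signal. An artefact of 1 probe set was argued against, since 4 of 4 Xist probe sets were higher on both arrays. Dilution of testis RNA by female gonads was argued against for the low Amh signal, as the Y-linked Uty and Eif2s3y differed by -0.0386 (SD 0.147) between numbers 1 and 2, where Amh differed by -2.57 (SD 1.48). That mean includes a Uty probe set that was not tested and read 11.7 to 27.9 at E13. The tested probe set of Uty read 650.3 and 706.4 on the arrays numbered 1, against 526.4 and 545.5 on those numbered 2. For Eif2s3y the values were 2363.1 and 2912.9, against 2594.5 and 3182.4. A small share of female tissue as the source of the Xist signal stays open. Younger gonads as a shared cause could not be decided. The correlation across probe sets of number 2 minus number 1 with E14 minus E13 was 0.167 for vehicle. It was -0.244 for vinclozolin, and -0.190 without E14 vehicle replicate 1, which went against such a cause. On the second principal component, read after the result was seen, the arrays numbered 2 (21.2 and 30.9) lay nearer to E14. There the arrays numbered 1 stood at 41.6 and 41.2 and the E14 arrays at -42.2 to -8.94.

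The gene list shifts at E14 may come from 1 vehicle array that stands apart, replicate 1, because 4 of the 14 lists were still called in the same direction without it. Vinclozolin replicate 1 stood apart too, and 7 of the 14 were called without it. Vehicle replicate 1 stood apart in the lists but lay near vehicle replicate 2 and vinclozolin replicate 2 on the first 3 principal components. Tissue beside the gonad cannot be told apart from other sources, since 78.6% of the mesonephros and adrenal list members had their highest E14 level on vehicle replicate 1, against 29.9% of all genes, but so did 83% of the ribosomal and 80% of the immediate early genes. All 4 lists were called as lower with vinclozolin, which favours a vehicle array, so the share of all genes is not a like baseline. Vehicle replicate 2 held the highest level for 2 of 18 mesonephros and 1 of 10 adrenal genes. The comparison with the ribosomal and immediate early lists was added after the share of 78.6% was seen. An effect of vinclozolin cannot be told apart from these, since 5 of the 14 medians kept their direction without vehicle replicate 1 and each group held 2 arrays.

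Of the 1183 probe sets higher with vinclozolin at E16 at an unadjusted p under 0.05, 54.2% had no gene symbol, against 26.0% of those tested. A shift of the low part of the signal scale was argued against as the whole cause, as 896 were still higher after quantile normalization, 57.5% of them without a symbol. The low signal of unnamed probe sets was argued against as well, since probe sets matched on mean signal gave 29.8%. The share fell to 42.1% without E16 vehicle replicate 2, so a part played by 1 array of the comparison stays open, and the count of 1183 itself was 585 and 1921 without vehicle replicates 1 and 2 and 572 and 849 without vinclozolin replicates 1 and 2. No biological explanation was tested.

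For the mean vinclozolin effect in utero, chance could not be excluded. Of 100 splits of the arrays within stage, the real one included, 100 gave as many probe sets past the threshold, which decides nothing as the real count was 0 (highest other 1250), 69 as many at an unadjusted p under 0.05 (real 923, highest other 4834) and 23 as many called lists (real 11, highest other 16). The split with 1250 calls parted both the E13 and the E14 arrays by their number, and the E16 arrays by treatment as in the real grouping. Of the 32 splits that parted the E13 arrays by number, 23 made calls, against 6 of the 68 others. Over those 68, the real one included, 38 gave as many at an unadjusted p under 0.05 (highest other 2415) and 10 as many called lists (highest other 12).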

How the results depend on the processing

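The alternatives with all arrays rescaled, with the E13 arrays numbered 1 left out and with a crossed pairing at E16 were chosen after the data were seen; the rest were planned. Outside the leave-one-out fits, named genes kept their direction and side of the threshold in 3746 evaluations, passed no longer in 244, passed newly in 10 and reversed in 7. Gene lists kept both in 957, lost their call in 237 and reversed in 2. In the leave-one-out fits the numbers were 1551, 162, 24 and 35 for genes, and for lists 270 kept, 127 lost and 19 reversed. Except where fewer arrays or other tested probe sets enter by construction, the cause was not tested. The nominal rule is not defined for the stage test or the difference between the compounds.

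With a pseudocount of 1 the counts of changed probe sets were 0 at E14, 5 at E16 and 4 with flutamide, and Insl3 at E13 stood at -0.040. With a pseudocount of 64, 1 probe set passed for the mean effect in utero, and Cyp17a1 between E13 and E14 stood at 0.0067. Quantile normalization put the ribosomal list at -0.0041 at E13 and 0.026 at E14, and the difference between the compounds for Amh at -0.015. Without a filter 419 probe sets changed between E13 and E14, and with a filter at the median 0 changed with vinclozolin at E14.

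Only the arrays of the comparison gave 0 at E14, and 268, 0 and 1796 for E16 minus E13, E14 minus E13 and E16 minus E14, with 2 residual degrees of freedom. Only the arrays of the experiment gave 998, 15 and 3075 for the same comparisons. The replicate block gave 3 at E14, 1 at E16 and 1360 between E13 and E14, and 0 for each compound in culture and for their difference. In culture the 2 gonads of an embryo were divided between compound and vehicle, but the labels do not say which arrays share embryos, and the block assumed that equal numbers do. The deviations of equal numbers correlated at 0.602 at E13, where all 4 arrays were closest to their own number, and at -0.0547 at E14, -0.112 at E16, 0.115 in the vinclozolin culture, where 2 of 4 were, and -0.00013 in the flutamide culture. No trend gave 292 between E13 and E14. Array weights gave 0 at E14, 3 with flutamide, and 1183, 184 and 3273 for the developmental comparisons in the order above. Both arrays of a group had the same weight, such as 0.735 for E14 vehicle, 0.535 for E14 vinclozolin, 2.208 for ethanol and 1.517 for flutamide. A single array that stood apart was thus not weighted down.

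The rule of unadjusted p with 1.5-fold and no overlap gave 226 at E13, 567 at E14, 1046 at E16, 368 and 325 for vinclozolin and flutamide in culture, 11 for the mean effect, 3284 for E16 minus E13 and 2853 for E14 minus E13, without adjustment for the number tested. With the E13 arrays numbered 1 left out, 1 probe set passed the stage test, 863 changed between E13 and E16 and 1046 between E13 and E14, and at E13 Cyp17a1 stood at 0.068, Insl3 at -0.54, Amh at -0.42 and the ribosomal gene Rps13 at 0.030. The crossed pairing gave 5 at E16, and rescaling changed no count by more than 1.5 times.

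Over the leave-one-out fits the counts ranged from 0 to 4 at E13, 0 to 272 at E14, 0 to 28 at E16, 0 to 9 for the mean effect, 0 to 1 for the stage test, 848 to 1574 for E16 minus E13, 71 to 746 for E14 minus E13 and 2846 to 2983 for E16 minus E14, and were 0 for vinclozolin, flutamide and their difference in culture. At E13, ranges that crossed 0 were -0.018 to 0.27 for Star, -0.68 to 0.20 for Cyp17a1, -0.42 to 0.76 for Insl3, -1.19 to 2.43 for Amh, -0.045 to 0.16 for the ribosomal and -0.0085 to 0.20 for the endothelial list. At E14 they were -0.67 to 0.057 for Cyp11a1, -0.10 to 0.87 for Cyp17a1, -0.59 to 0.33 for Insl3, -0.097 to 1.77 for Amh, -0.0094 to 2.47 for Sall4 and -2.04 to 0.15 for Rarb. The lists at E14 ranged from -0.00060 to 1.16 (Sertoli), -0.018 to 0.74 (germ cell), -1.31 to 0.24 (erythroid), -0.70 to 0.011 (mesonephros), -0.99 to 0.086 (adrenal), -1.12 to 0.15 (retinoic acid), -0.75 to 0.084 (immediate early), -0.42 to 0.040 (Wnt), -0.48 to 0.033 (TGF-beta) and -0.19 to 0.075 (respiratory chain).

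For vinclozolin in culture the ranges were -0.37 to 0.0025 for Star, -0.24 to 0.011 for Cyp11a1, -0.28 to 0.23 for Cyp17a1, -0.38 to 0.17 for Insl3, -0.67 to 0.39 for Amh, -0.0064 to 0.45 for Rpl34 and -0.030 to 0.34 for the ribosomal list. For flutamide they were -0.34 to 0.016 for Amh, -0.10 to 0.31 for Insl3 and -0.15 to 0.020 for the respiratory chain list, and for the difference between the compounds -0.50 to 0.0061 for Cyp17a1, -0.51 to 0.55 for Amh and -0.49 to 0.069 for Insl3. For the mean effect they were -0.20 to 1.01 for Amh and -0.066 to 0.18 for Cyp11a1. Between E13 and E14 they were -0.49 to 0.44 for Cyp17a1, -0.14 to 0.020 for the respiratory chain, -0.0051 to 1.23 for the erythroid, -0.18 to 1.10 for the retinoic acid, -0.29 to 0.024 for the cell cycle and -0.034 to 0.55 for the Wnt list, and between E14 and E16 -1.36 to 0.50 for Amh.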

Other observations

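The vehicle testes of the cultures, which started at E13 and ran for 3 days, were set beside the vehicle testes in utero after all arrays had been rescaled to 1 trimmed mean. No test was made, since culture and array set cannot be separated, and the genes were chosen after their values were seen. The Leydig genes shown had higher levels than at E13. On the log2 scale Cyp11a1 stood at 9.22 in the DMSO culture and 10.42 in the ethanol culture, against 5.25 at E13 and 10.96 at E16. Cyp17a1 stood at 9.62 and 10.13, against 4.83 and 12.03, Hsd3b1 at 11.96 and 12.61, against 6.90 and 12.50, Insl3 at 7.90 and 8.07, against 4.59 and 10.07, and Star at 9.17 and 9.61, against 6.66 and 9.03. The median difference of the Leydig list, DMSO culture minus in utero, was 1.46 against E13 and -0.51 against E16.

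Other cell types stood differently in the DMSO culture. Sertoli genes had a median difference of 1.05 against E13 and 0.56 against E16, germ cell genes of -0.92 and -1.34, endothelial genes of -0.72 and -0.90, erythroid genes of -2.20 and -2.85 and peritubular genes of -0.22 and -1.48, with Acta2, smooth muscle actin, at 7.98 in culture and 8.02 and 10.40 at E13 and E16. In the ethanol culture the medians against E16 were 0.02 for Leydig, 0.21 for Sertoli, -0.57 for germ cell, -0.11 for endothelial, -2.20 for erythroid and -1.38 for peritubular genes. The ethanol culture arrays had beta-actin 3' to 5' ratios of up to 11.1, against up to 3.12 in the DMSO culture, so RNA quality differed between the cultures too. Sycp3 stood at 5.99 in the DMSO culture, against 6.78 at E13 and 9.60 at E16. The cultures also differed from each other, with Fos at 6.38 in DMSO and 11.29 in ethanol and Egr1, another immediate early gene, at 9.26 and 12.16.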
